A study of Homo sapiens with 6 samples.

How the data were processed

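CTCF binding was profiled by chromatin immunoprecipitation and sequencing in HCT-116, a human colon cancer cell line. The series holds 6 samples, of which 3 are CTCF libraries (wild-type cells, clone D3 and clone E4) and 3 are libraries made without antibody from the same populations. The no-antibody libraries were not analysed here. Each population had 1 CTCF library.

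Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, complexes were purified with an antibody against CTCF, and the libraries were sequenced with paired ends on a NovaSeq instrument. The submitters' processing notes name CASAVA 1.8.2, Picard 2.23.1, bedtools 2.29.2 and MACS2 2.2.7.1 and the genome build hg19, without a role or an order. The aligner, the settings of the peak call and the use of the no-antibody libraries as controls were not given in the sources used here. The authors deposited 1 list of broad peaks per library in the 9 columns of the broadPeak layout, so peaks were called per sample and not on pooled samples. The fold enrichment per peak, a ratio of the signal over the peak caller's own background, is the authors' value. The −log10 p and −log10 q values per peak are also those the authors deposited, and the lowest −log10 q in the lists lay just above 1, which corresponds to a q of 0.1. The score column that the authors deposited equals 10 times the −log10 q without its decimals in over 99.9% of the peaks of each list and was not used. These values depend on the depth and background of their own library. They were therefore used only to describe, rank or filter peaks within their own list.

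Read numbers were not in the tables used here, so the depth of each library is unknown. The number of peaks in a list moves with depth and with the efficiency of the immunoprecipitation. For this reason list lengths were not read as binding levels, and the lists were also compared at equal length, 38645 peaks, which is the length of the shortest list. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only and not the spread between cultures. No p-values were computed, because there is 1 library per population.

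Chromosome names and the end of the last peak on chromosome 1 were checked against the named build. Peaks counted as shared when they overlapped by at least 1 bp. As background, the other list was shifted by 100 kb and by 200 kb up and down the chromosome, and the mean share over the 4 shifts is given. Overlapping peaks of the 3 lists were merged into regions, and each region was assigned to the libraries with a peak in it. WT peaks without a peak in either clone were counted beside the number that independent lists would give, over all WT peaks and summed within deciles of the WT −log10 q. Both clone comparisons use the same WT library, which cannot be split, so part of any excess over independence may come from it. Clustering was counted in 10 Mb bins with 50 or more WT peaks, where a bin stood out if the interval of its share lay above 2 times the share over the genome.

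Gene windows were written from general knowledge of hg19, since no hg19 annotation was used here, and they carry no exon or intron assignment. A table of RefSeq genes on another assembly was used only for names and neighbours. All 50 single genes of the windows were found in it on the same chromosome, and their order was the same on 18 of 18 chromosomes. Genes were taken with 10 kb on either side. The 6 gene lists (8q24 genes, WNT targets, insulator and cluster loci, CTCF and cohesin genes, colon epithelial genes and colorectal cancer genes) were set beside 10000 random draws of as many WT peaks matched on deciles of −log10 q.

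The rule for named sites, the gene lists, the comparisons and most alternatives were fixed before the data were examined. Named sites were every region within 10 kb of CCAT1 or MYC, the 5 peaks of highest fold per list, the 10 strongest WT peaks with no clone peak within 1 kb, and the 10 strongest regions of both clones with no WT peak within 1 kb, of which the first few are given with coordinates. Of each gene list, members whose presence differed between libraries were named together with members holding most WT peaks, and 1 member is not reported here by name. The following were added after values had been seen: the peaks missing from a single clone, the draws per clone, the protocadherin count, a run of peaks on chromosome 19, the ranks along chromosome 8, the mean overlap of the clones less their mean overlap with WT, and the alternatives for the CCAT1 peak. Ranks along chromosomes were computed within the regions called in all 3 lists, so that the lists had equal length. The difference in rank between WT and a clone was taken per region and its median per bin, and for sets of regions the median has a bootstrap interval from 10000 resamples of regions, which leaves out the spread between cultures.

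Alternatives were a −log10 q of 5 or more in every list, coverage of 50% of the peak (of the merged region where regions were counted), a distance of up to 1 kb, equal or full list length, ranking by fold, 50 kb around genes and 5 Mb bins. Equal lists of 10000 and of 20000 peaks were added later. Coordinates are 1-based on hg19. The overlap code was tested on simulated clones made from the WT list of 38645 peaks. It recovered 295 of 295 removed peaks, 200 of 200 added peaks and the 1 planted block, and it matched 500 of 500 overlaps checked by direct search. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.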

Results

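CTCF, the zinc-finger protein that binds insulators and anchors chromatin loops together with cohesin, was mapped in HCT-116 human colon cancer cells. Wild-type cells (WT) were set beside D3 and E4, a pair of clones whose genotype the labels give as a CTCF mutation. Where the mutation lies is not stated in the labels, while the series' title concerns a distal CTCF site and the WNT-dependent gating of the oncogene MYC. Each population had 1 CTCF library, so no difference has a replicate check. The list of D3 held 57935 peaks covering 55.4 Mb, that of E4 39434 peaks covering 32.9 Mb, and that of WT 38645 peaks covering 28.5 Mb. Median peak widths were 873 bp, 750 bp and 639 bp. The authors' −log10 q had a median of 8.66 in D3, 7.71 in E4 and 5.33 in WT, and 32.5%, 34.1% and 47.0% of the peaks lay under 5. With a −log10 q of 5 or more the lists held 39100, 25983 and 20501 peaks. The 5 peaks of highest fold in each list were all called in both other lists. They were led by chr5:70585605-70586266 in D3 (fold 50.2), chr8:7468088-7469466 in E4 (fold 39.4) and chr16:28761271-28761863 in WT (fold 25.9).

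The first question was whether CTCF peaks around MYC differed between the clones and WT. At CCAT1, a long non-coding RNA locus in the colorectal super-enhancer upstream of MYC, WT had a peak at chr8:128226838-128227809 that neither clone had. This 972 bp peak had a fold of 7.15 and a −log10 q of 9.39, at the 75.4th percentile of the WT list, and it lay 520 kb from the peak at the MYC promoter. The nearest clone peaks were 5.53 kb away in D3 and 6.15 kb away in E4. A neighbouring CCAT1 region, chr8:128218769-128221305, was called in all 3 libraries, as were the 3 regions within 10 kb of MYC.

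Among the 1427 WT peaks missing from both clones, the CCAT1 peak had the highest −log10 q. Of the 9519 WT peaks at least as strong, it was the 1 peak that both clones lacked. The third region near CCAT1, chr8:128210672-128211467, was called in WT only and had a fold of 2.97, at the 0.0828th percentile of the WT list. The MYC regions were chr8:128737486-128738584, chr8:128745794-128746939 and chr8:128748113-128750363, the last of them at the promoter. The middle region lay at the 79.8th percentile of D3, the 90.5th of E4 and the 84.3rd of WT. A region over CCAT2 and CASC8, chr8:128412434-128414866, was also called in all 3 libraries, at the 81.8th, 79.6th and 89.4th percentile of D3, E4 and WT.

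Over the whole window from FAM84B to PVT1, which held 39 regions, 22 of 32 WT peaks were overlapped by both clones and 1 by D3 only. The other 9, or 28.1% (13.7 to 46.7), had no clone peak. Of the 16 WT peaks with a −log10 q of 5 or more, both clones kept 15, and the CCAT1 peak was the exception. The other 8 missing peaks had a −log10 q of 1.09 to 4.74. No region of the window was called in both clones and not in WT. The absence of the CCAT1 peak from the clones could not change under the alternatives. These removed clone peaks, asked for more overlap or allowed a distance of 1 kb, which the nearest clone peaks exceeded. The rank of this peak among missing WT peaks moved from 1 to 4 with a −log10 q of 5 or more in every list. It moved to 26 when 50% of the peak had to be covered. Each of the 21 regions of this window called in all 3 libraries was also ranked within such regions, and the median difference between its rank in WT and in D3 was 18.3 percentile points (bootstrap 95% interval 8.56 to 23.6), with WT higher. The same difference for E4 was 12.2 points (−3.38 to 15.0), and 5 Mb bins of other chromosomes reached 6.02 and 6.25 at the upper end of their central 95%.

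**Figure D1:**
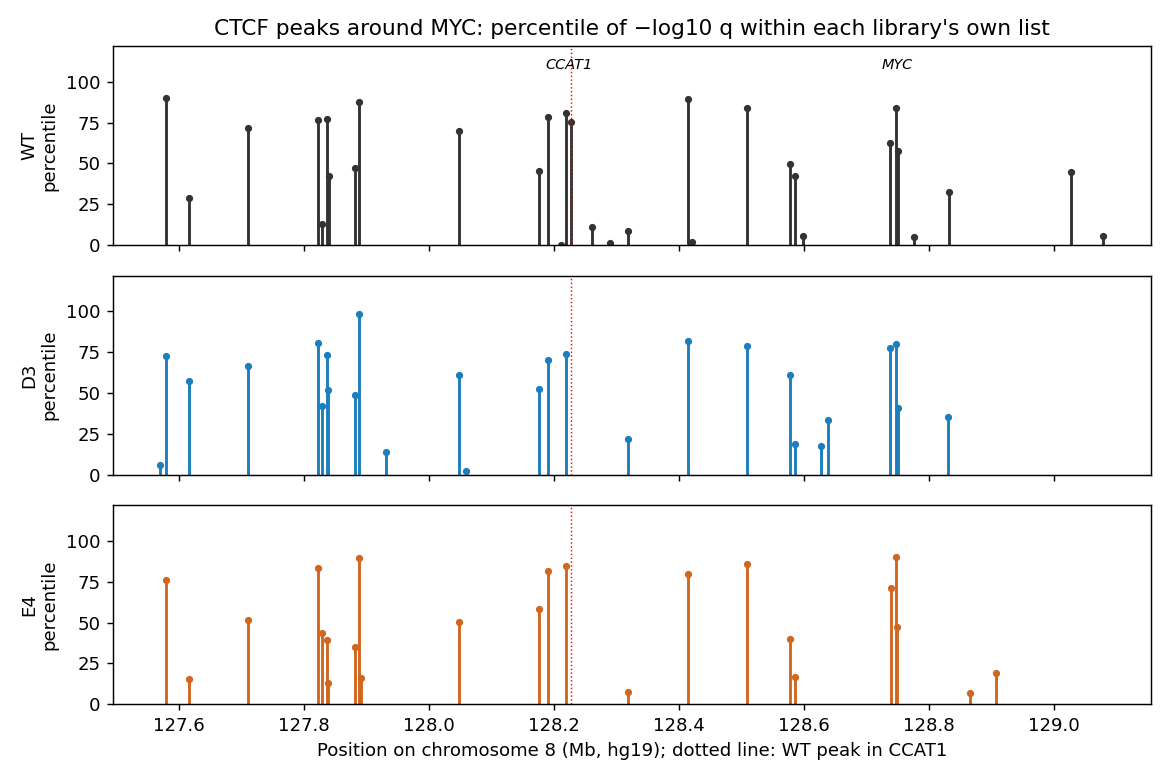
CTCF peaks from FAM84B to PVT1 on chromosome 8 (x axis, Mb, hg19) in WT, D3 and E4, drawn as the percentile of −log10 q within its own list (y axis, 0 to 100) for the strongest peak of each region. The dotted line marks the CCAT1 peak of WT at the 75.4th percentile, where neither clone has a peak, while the 3 regions near MYC have peaks in all 3 libraries.

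The next comparison asked how far each clone kept the CTCF peaks of WT cells. D3 peaks overlapped 95.9% of the WT peaks (95.7 to 96.1), and E4 peaks overlapped 85.7% (85.4 to 86.1). With the clone peaks shifted along the chromosome these shares were 5.13% and 3.36%. WT peaks that a clone lacked were mostly weak. In the weakest decile of the WT list, 26.9% had no D3 peak and 57.9% had no E4 peak, against 0% and 0.0259% in the strongest decile. At equal list length D3 overlapped 86.7% and E4 85.3% of the WT peaks, which brought the clones closer together. The list of E4 was shorter than that of D3, so the gap at full length was not read as a difference in binding.

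Both clones lacked 1427 WT peaks, 3.69% of the list (3.51 to 3.89). D3 lacked 1566 and E4 5519. Independent lists would share 224 missing peaks, or 751 when counted within deciles of −log10 q. Of the 1427 peaks, 1294 (90.7%) came from the weakest 2 deciles, and 6 were among the 20501 WT peaks with a −log10 q of 5 or more. After the CCAT1 peak, these were chrX:112003966-112004369, chr11:63933023-63933390, chr17:58103941-58104218, chr10:134036520-134037038 and chr12:117393561-117394004, with a −log10 q from 8.29 down to 5.15. A peak in PVT1, the non-coding RNA gene next to MYC, ranked eighth (chr8:129026970-129027334, −log10 q 4.74). The count was 111 when the clone lists were held to a −log10 q of 5 or more as well, and it rose to 3285 at equal list length. Both clones were compared with the same WT library, so part of the excess over independence may come from it.

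**Figure D2:**
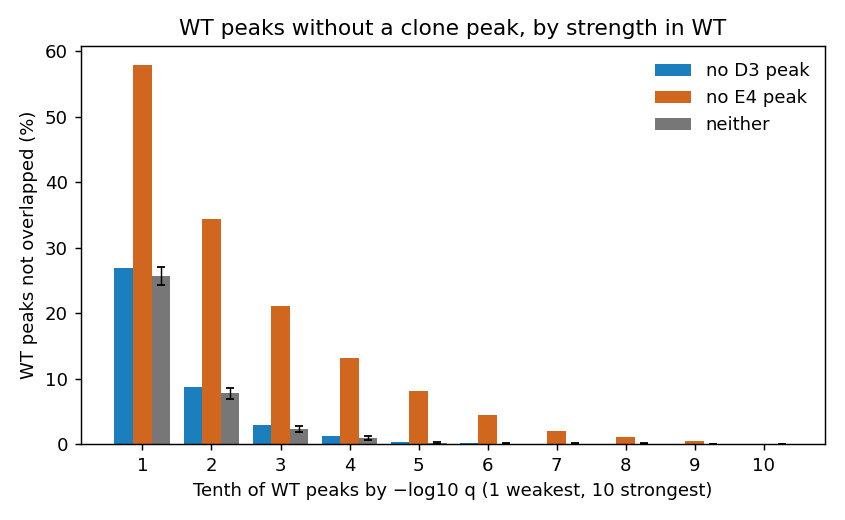
Share of WT peaks (y axis, %) without a D3 peak, without an E4 peak and without either, by decile of the WT list ranked by −log10 q (x axis, 1 weakest to 10 strongest). Error bars are exact 95% intervals of the share missing from both clones, which falls from 25.7% in the weakest decile to 0% in the strongest.

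Regions that both clones had and WT lacked were counted next. They numbered 5605 of the 38100 regions called in both clones, or 14.7% (14.4 to 15.1), and 5585 of them had no WT peak within 1 kb. Of these regions 636 had a −log10 q of 5 or more in both clones. The one ranked first was chrY:21154585-21155057, with a fold of 12.5 in D3 and 10.5 in E4, on a chromosome whose content in each population was not examined. It was followed by chr3:182428047-182429169 (9.15 and 8.53), chr14:54413204-54413829 (7.32 and 8.35) and chr10:103048088-103048667 (10.7 and 6.70). None of the first 10 lay in a window of the gene lists. In the weakest decile of the regions called in both clones 59.0% lacked a WT peak, and in the strongest 3 deciles 1 of 11430 did. When a library's peaks had to cover 50% of the merged region the count was 11842, and equal list length gave 2818. The 11842 include regions that hold a WT peak too narrow to cover 50% of them, and WT peaks had the smallest median width (639 bp). Of all 60235 regions, 32495 (53.9%) were called in all 3 libraries, 15717 in D3 only, 3988 in D3 and WT, 1427 in WT only, 873 in E4 only and 130 in E4 and WT.

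Whether the clones resembled each other more than WT was asked at equal list length. E4 overlapped 86.7% of the D3 peaks (86.3 to 87.0), and D3 overlapped 87.3% of the E4 peaks (87.0 to 87.6). The mean for the pair of clones was 87.0% and the mean of both clones with WT was 85.5%. D3 with WT gave 85.3% and 86.7% in the 2 directions, and E4 with WT gave 84.7% and 85.3%. The difference between these means was 1.19 to 1.43 percentage points in 5 of 7 alternatives and 4.19 points with 50% coverage. The 50% rule depends on peak width as well, and the whole WT list had the smallest median width (639 bp, against 873 bp in D3 and 750 bp in E4). The larger value was therefore not read as a closer likeness of the clones. The difference turned to −0.328 points at full list length, where the lists are unequal.

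The gene lists asked which known loci kept their CTCF peaks. The 8q24 genes had the largest share, with 5 of 14 WT peaks missing from both clones against a mean of 1.07 in matched draws. The draws took single peaks from the whole genome, while the 14 peaks are neighbours in 1 segment, so the draws describe this excess and do not test it. The 10 Mb bin that holds these genes lacked 14.4% of its WT peaks, more than the genome as a whole. Of these 5 peaks, 2 were near CCAT1 and 2 near PVT1. The fifth was a weak peak at chr8:128420679-128421586 near CASC8, CCAT2 and POU5F1B, the latter a retrogene of the stem cell factor POU5F1. MYC kept 4 of 4 WT peaks in both clones, and PCAT1 and PRNCR1 had no peak in any library.

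At WNT target genes D3 overlapped 26 of 26 WT peaks and E4 24 of 26. None was missing from both clones, and matched draws had a mean of 0.763 such peaks. Both clones overlapped 92.3% of its WT peaks (74.9 to 99.1), against 85.4% of all WT peaks. ZNRF3, an antagonist of WNT receptors, kept 5 of 5 WT peaks in both clones. The receptor gene EPHB2 kept 4 of 4, and the WNT inhibitor gene NKD1 kept 3 of 4 in both and the fourth in D3. ASCL2, an intestinal stem cell factor, had 1 peak in D3 and none in E4 or WT, and none in D3 at equal list length. At the 5 CTCF and cohesin genes 13 of 15 WT peaks were overlapped by both clones, with 5 of 5 at STAG1 and 4 of 4 at NIPBL. RAD21, which encodes a cohesin subunit, had 3 peaks in D3, 2 in WT and none in E4, and its strongest WT peak lay at the 11.4th percentile. RAD21 lies on chromosome 8 between 115 and 120 Mb, where the median difference in rank of regions called in all 3 libraries was 16.2 points between WT and E4, with WT higher and a limit of 6.25 from other chromosomes. All 8 WT peaks at colon epithelial genes were in both clones, among them 2 each at CDX2, CEACAM5 and KRT8. KRT20, a keratin of differentiated colon cells, had 2 peaks in each clone and none in WT, and VIL1 had none in any library. At equal list length D3 had no KRT20 peak and E4 had 2. All 9 WT peaks at colorectal cancer genes were in both clones, with 2 each at APC and SMAD4, and CTNNB1 had no peak in any library.

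At insulator and cluster loci 53 of 73 WT peaks were overlapped by both clones and 4 by neither (matched mean 3.36). HOXB kept 10 of 10 in both clones. HOXA, like HOXB a cluster of developmental transcription factor genes, kept 7 of 10, and the tumour suppressor gene RB1 had 1 peak in D3 only. The protocadherin cluster, where CTCF takes part in promoter choice, held 18 WT peaks, of which D3 overlapped 17 and E4 8. Over all lists 9 of 145 WT peaks were missing from both clones, against 4 of 131 without the 8q24 genes. The 9 became 3 with a −log10 q of 5 or more, 16 at equal list length and 14 with 50 kb around the genes.

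The last comparison asked whether missing peaks lay in blocks. Of 273 bins of 10 Mb, 9 had a share of missing WT peaks whose interval lay above 2 times that of the genome. They lay on chromosome 8 (100 to 110, 120 to 130 and 140 to 150 Mb), chromosome 10 (110 to 130 Mb), chromosome 16 (80 to 90 Mb) and chromosome 17 (50 to 60 and 70 to 90 Mb). In these bins 317 of 1998 WT peaks (15.9%) were missing from both clones, against 3.03% elsewhere, and the bins ranged from 12.7% to 23.1%. From the strength of their peaks 132 would be missing, so the observed number was 2.40 times as high, in bins that were picked for their excess. The bin from 120 to 130 Mb of chromosome 8, which holds CCAT1 and MYC, lacked 28 of 194 (9.81% to 20.2%). With a −log10 q of 5 or more in every list no bin stood out, and at equal list length 5 did. The stricter setting left 168 bins to test and 111 missing among 20501 WT peaks. With so few missing peaks a bin could hardly stand out, so this does not show that clustering is absent among strong peaks.

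Ranks along chromosome 8 were looked at after these bins were known. Among regions called in all 3 libraries, the median of the differences in rank between WT and E4 was 8.12 to 22.4 percentile points in the 13 bins of 5 Mb from 85 Mb onwards, with WT higher in each. Bins of other chromosomes reached 6.25 at the upper end of their central 95%. For D3 the median difference was 8.50 to 16.7 points in the 4 bins from 130 Mb onwards, where that limit was 6.02. Before these points 0 of 16 bins in E4 and 0 of 25 bins in D3 lay above the limit. A bin can hide a smaller stretch. The 21 shared regions from FAM84B to PVT1, before 130 Mb, ranked lower in D3 by 18.3 points (8.56 to 23.6). The bin from 125 Mb that holds them gave 4.42. The starting points were chosen after the values were seen.

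**Figure D3:**
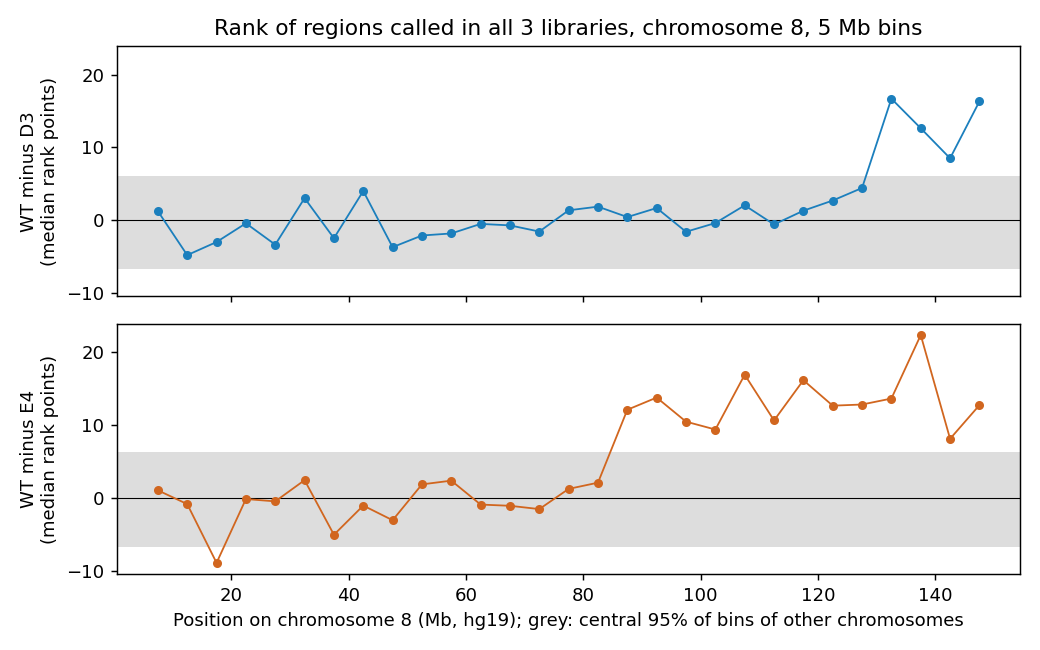
Median difference in percentile rank (y axis, WT minus clone) of regions called in all 3 libraries, in 5 Mb bins along chromosome 8 (x axis, Mb, hg19), for D3 and E4. Grey bands span the central 95% of bins of other chromosomes, and E4 lies above its band from 85 Mb and D3 from 130 Mb.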

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

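The window of APP, the amyloid precursor gene, stood out because its numbers of peaks in the clones lay on opposite sides of WT, a check made after the lists had been seen. D3 had 7 peaks, E4 3 and WT 4, so that D3 and E4 differed by 4 peaks, and at equal list length the numbers were 5, 3 and 4. The difference was not tested, since each population had 1 library. Of the 56 windows, 4 others (HOXA, protocadherin, KCNQ1 and RAD21) also had D3 above and E4 below WT at full list length, and none of these 4 did at equal length.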

How the results depend on the processing

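The alternatives for the CCAT1 peak, the difference between overlaps, and lists of 10000 and 20000 peaks were chosen after seeing the data. Of 55 alternatives, 25 stayed within the interval of the value or within 1.5 times the count, 29 moved and 1 reversed. No paired analysis was possible because the groups share only replicate number 1, and with 1 library per group none could be left out. Neither clone had the CCAT1 peak in any of its 4 alternatives, which are counted among the 25. None of the 4 could have added a clone peak there, so this outcome was fixed and shows no robustness. With a −log10 q of 5 or more, E4 and WT held 25983 and 20501 peaks, D3 and E4 overlapped 99.2% and 91.2% of WT peaks, 111 were missing from both clones (1 of them around MYC, 3 in the gene lists), 0 bins stood out, the CCAT1 peak ranked 4, and E4 overlapped 83.1% of D3. This setting filters the clone lists as well: of the 20501 WT peaks, 6 were missing from the whole clone lists. With 50% coverage the overlaps with WT were 94.1% and 81.5%, that of D3 by E4 72.3%, the difference between overlaps 4.19 points and the rank of the CCAT1 peak 26. Regions that both clones covered to 50% and WT did not numbered 11842. Within 1 kb, D3 overlapped 96.2%. At equal list length the overlaps with WT were 86.7% and 85.3%, with 3285 WT peaks missing, 2818 regions of both clones without WT, 16 missing peaks in the gene lists and 5 bins. With 50 kb around genes 14 of 259 peaks were missing, and 14 bins of 5 Mb stood out. E4 overlapped 66.0% of D3 at full length, 85.7% by fold, and 77.0% and 83.0% with 10000 and 20000 peaks. The difference between overlaps reversed to −0.328 points at full length. Beyond what list length and filtering set by construction, the cause of these moves was not tested. Unknown depth limits what can be said of weak peaks.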

Other observations

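All tests in this part, with their thresholds, were chosen after the results had been seen, and chromosome 8 was divided into segments and by clone after a joint test over both clones had decided nothing. They describe these libraries and have no replicate check.

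Of the 18 WT peaks at the protocadherin cluster, E4 lacked 10, against a mean of 4.07 in draws matched on strength, and D3 lacked 1, against a mean of 1.29. The difference between the clones was not tested. In all, the cluster held 31 peaks in D3, 10 in E4 and 18 in WT, and at equal list length 18, 9 and 18. Without it, E4 lacked 9 of the 55 other WT peaks at insulator and cluster loci, where draws had a mean of 7.41. The cluster was singled out for its value among 56 gene windows in 2 clones, so the draws describe it and do not test it.

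A run of peaks on chromosome 19 was missing from E4. The strongest WT peak without an E4 peak was chr19:21665877-21666910, at the 99.7th percentile of the WT list, and it was the 1 peak of the strongest WT decile that E4 lacked. D3 called this peak at the 95.1st percentile of its own list. Its fold in WT was 5.54, near the median of 5.24 of the WT list, so its high place rests on −log10 q and not on fold. All 5 WT peaks between chr19:21190703 and chr19:21711650, within a region rich in zinc-finger genes, had no E4 peak, while D3 had 4 of them. The ends of this stretch were chosen after the values were seen. Its peaks at chr19:21438519 and chr19:21711368 were weak, at the 2.27th and 7.13th percentile of the WT list. In that weakest decile E4 lacked 57.9% of the WT peaks of the whole genome. The strongest WT peaks missing from D3 and called in E4 were chr18:78015600-78016184 and chr20:62406382-62407022, at the 83.3rd and 79.7th percentile of the WT list.

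The CCAT1 peak of WT had no counterpart in either clone. A weak call near the threshold would have a low −log10 q, whereas this peak had 9.39, at the 75.4th percentile of the WT list. Of the 1000 WT peaks nearest in −log10 q, 0% were missing from both clones (upper bound 0.368%). The next missing peak had a −log10 q of 8.29, so this 0% restates the rank of the CCAT1 peak and is no separate test. A lower signal over the whole window remains open. D3 still called 14 and E4 13 of the 22 WT peaks there that were weaker than the CCAT1 peak. A drop that removed every weaker peak was therefore not seen, but a smaller one is not excluded by these counts. Of the WT peaks in the window 28.1% were missing from both clones, against 3.69% over the genome. Shared regions of the window ranked lower by a median of 18.3 points in D3 (8.56 to 23.6, limit 6.02) and 12.2 in E4 (−3.38 to 15.0, limit 6.25). Those of the 5 Mb bin from 125 Mb ranked lower by 4.42 and 12.8. The mutation that the labels give to both clones also remains open and was not tested: its position is not stated in the labels, and the sequence of the clones at this site, which would decide it, was not analysed here. A chance feature of the single WT library remains open too.

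Missing WT peaks clustered in 9 bins of chromosomes 8, 10, 16 and 17, which an uneven spread of weak peaks did not give, since 1000 reassignments among peaks of like strength reached at most 2 bins. On chromosome 8 from 100 to 110 and from 120 to 130 Mb shared regions ranked below WT by a median of 12.7 points in E4 and 2.28 in D3 (upper bound 4.42). The limits from other bins were 4.01 and 4.59. A lower dosage in E4 alone would not account for peaks that D3 lacked too. In D3 a lower dosage before 130 Mb remains undecided, since its shared regions around MYC ranked lower by 18.3 points. The bins from 90 to 100 and 110 to 120 Mb dropped by 12.3 and 13.4 in E4. Of their WT peaks 6.88% and 4.85% were missing from both clones, which cannot test a drop in E4 alone. From 140 Mb the medians were 10.5 in E4 and 10.7 in D3, with median ranks of 81.2 in WT, 63.7 in D3 and 62.9 in E4. A lower dosage in both clones and a higher one in WT would both give this and cannot be told apart here. On chromosomes 10, 16 and 17 the medians over the 983 shared regions of the 6 bins were 1.09 in E4 (0.551 to 2.13) and −0.277 in D3 (upper bound 0.249). This argues against a lower dosage of these bins as a set that would reach the limits of 4.01 and 4.59. A smaller drop in E4 remains open, and 1 bin (chromosome 10, 120 to 130 Mb) lay just above the limit in E4. Regions called in E4 only were not frequent in these bins (1.83%, upper bound 2.96%, against 3.03% of the regions called in all 3), and those in D3 only gave 2.48%. This cannot decide whether weak calls favour these bins in every library. Such regions leave out any place with a WT peak, and the bins were picked by WT peaks. HCT-116 is known to carry extra copies of parts of these 4 chromosomes, and whether the WT list was made with another background correction than the clone lists remains untested.

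Regions called in both clones and not in WT were numerous but weak. Among the strongest 3 deciles of regions called in both clones 0.00875% lacked a WT peak (upper bound 0.0487%). The regions without a WT peak were thus weak in the clones, which missed calls in WT and weak gained sites would both give. The WT list as a whole held 18144 peaks with a −log10 q under 5, more than E4 (13451) and fewer than D3 (18835). It held the fewest peaks at 5 or more, 20501 against 25983 in E4 and 39100 in D3. The depth of each library is unknown, so the share does not decide between these readings. Sites gained in the clones remain possible for single regions and were not tested.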
